A study of Mus musculus with 2 samples.

How the data were processed

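The samples were 2 biological replicates of P0 mouse forebrain, each from pooled mice of both sexes, processed by ATAC-seq with Nextera tagmentation. Per the labels, the reads were aligned to mm10. The authors' processed files were 12 peak lists in narrowPeak or IDR format: 3 for each sample, and 6 for the series, drawn from the alignments of both samples. Each sample had an IDR-thresholded, a looser pseudoreplicated and an IDR-ranked list, and the series had thresholded, conservative, replicated and pseudoreplicated lists and 2 ranked lists. The peak caller, its version and its settings are not given in the sources used here, and neither is the content of 1 further file from which the authors derived each unranked list. The deposited signal value of a peak has no stated scale, so it was ranked or compared within a list, with the exception of 1 test of depth that matched peaks of separate lists at equal signal. The deposited score ran from 540 upwards in the thresholded lists, and a score of 540 corresponds to an IDR of 0.05. The deposited −log10 q value of each peak was used for 1 alternative and 1 test. The number of reads per sample is not given in the sources used here, so the depth is unknown, and precision is given as 95% Wilson intervals, which cover counting error only.

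Peak lines that touched or overlapped were merged into regions, since 1 interval can carry several summits, and each region took the signal and summit of its strongest line. The joint IDR-thresholded list of the series was the main list, and each sample's own thresholded list gave the replicate values. Regions were placed on the GENCODE M21 basic annotation of GRCm38, the assembly behind mm10, with 21827 protein-coding genes and 41406 TSSs. A promoter region lay within 500 bp of a TSS, and regions outside promoters were classed as exon, intron or intergenic. A distal region lay over 2000 bp from every TSS of these protein-coding genes, whichever of these classes it fell in. Start sites of other genes were not used, so a region at such a site could count as distal. Positions are counted from 1.

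Regions of 1 replicate were called found in the other when at least 50% of their length was covered, and 100 circular shifts of the other replicate's regions along each chromosome gave the share due to position alone. Signals of the 25612 regions paired between the replicates were ranked for Spearman's correlation. The 21 gene lists, chosen from textbook knowledge, held 450 symbols, of which 449 matched the annotation, with Ahsp left out. A gene's promoter counted as accessible when any of its TSSs lay within 500 bp of a region, so 1 region can count for several neighbouring genes. The share of each list was placed among 10000 random lists of the same size, with ties counted as 0.5. A list was called above or below the random lists outside their central 95%. Distal regions were assigned to the nearest protein-coding TSS within 100 kb, and the median number per gene was placed among 10000 random lists matched in 10 bins on the length of sequence nearest to each gene. No p-values were computed, since the design has 1 group and neither genes nor regions are replicates.

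For 19 consensus motifs, windows reaching 100 bp to either side of the strongest summit were searched on both strands in the GRCm38.p6 sequence, and the share with a match was divided by the mean share in windows of the same width centred 1000 bp to either side. A count of 0 was given with the limit that 3 matches would set. The 10 shuffled versions of each motif, with the same letters in another order, were searched in the same way. Mitochondrial matches were found with blastn 2.17.0 against the mitochondrial sequence of the same assembly, and a region was called matching at 50% of its length or more. The other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

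The genes named were set by a rule. It took the 3 members of each list with the strongest promoter regions, and in lists under 50% accessible up to 3 more with or without one. It also took the 20 genes with the most distal regions and the 2 leading members of each list, the 5 strongest regions of all and of the distal class, and up to 3 listed genes per replicate accessible in that replicate alone. Names outside the rule are disclosed together, where the 21 lists are summed up. The lists, motifs, windows, thresholds, naming rule and most alternatives were chosen before the data were examined. The alternatives were other overlap rules, promoter windows, assignment distances, TSS sets, random lists and motif windows, the stricter and looser lists, every line counted without merging, and each replicate alone. Comparing equal numbers of the strongest regions was added after the data were seen, and so were 23 gene families defined by symbol patterns, which were fixed before their values were computed.

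The procedures were tested on simulated data. A planted overlap of 60% was recovered as 60%. Of 200 random gene lists of 20 genes, 4.5% fell outside the central 95% for promoters and 0.5% for distal regions. Of 200 lists with 95% accessible promoters 97% were called, and of 200 lists with a 3-fold excess of distal regions 56% were called. All windows with a planted motif were found, and 1.21% of the other windows matched by chance. The ranked lists and the replicated list were left out of the comparisons, and the ranked lists were used in 1 check of the thresholded lists.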

Results

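Open chromatin was mapped by ATAC-seq, in which the Tn5 transposase cuts and tags accessible DNA, in the forebrain of mice at postnatal day 0 (P0). The 2 samples formed 1 group of biological replicates. Replicate 1 was a pool of 15 mice of both sexes, and replicate 2 was also a mixed-sex pool, of a size the labels do not state. The labels name no further condition, so the comparisons set the replicates against each other, gene groups against random genes, and region summits against their flanks. The joint list of both replicates, thresholded on the irreproducible discovery rate (IDR), held 50722 accessible regions on the mouse build mm10. These covered 39.3 Mb, which is 1.44% of the genome, with a median width of 723 bp. Replicate 1 alone gave 44331 regions covering 33.4 Mb, and replicate 2 gave 28342 regions covering 23.2 Mb. The number of reads behind each list is not given in the sources used here, so the depth of each sample is unknown, and the intervals printed cover counting error only.

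Accessible regions were concentrated at gene starts. Of the 50722 regions of the joint list, 12940 (25.5%, 95% Wilson interval 25.1 to 25.9) lay within 500 bp of a transcription start site (TSS) of a protein-coding gene, a class that makes up 1.04% of the genome. A region counted as promoter by its nearest edge, while the genome share counts bases, so 1.04% understates the share due to position alone. Regions outside promoters were classed by their summit. Introns held 33.8% of the regions and 35.0% of the genome, exons 2.68% and 2.40%, and intergenic sequence 38.04% and 61.6%. Promoters dominated the strongest regions: they made up 80.9% of the decile with the highest peak signal and 11.8% of the decile with the lowest. The promoter share was 28.5% in replicate 1 and 40.9% in replicate 2, a mean of 34.7% ± 8.76 (SD, n = 2). The number of promoter regions differed less, at 12621 and 11582, than the number of distal regions over 2000 bp from any protein-coding TSS, at 30366 and 15950. In the looser joint list the promoter share was 13.7%.

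Most of the regions of replicate 2 were also found in replicate 1. With at least 50% of a region's length covered by a region of the other replicate, 93.1% of replicate 2 regions (95% interval 92.8 to 93.4) were found in replicate 1, and 58.3% of replicate 1 regions (57.8 to 58.7) were found in replicate 2. Shifting the other replicate's regions along each chromosome gave mean shares of 1.19% and 0.861%. The share rose with peak signal. In replicate 1, 99.0% of the strongest decile and 23.7% of the weakest decile had a counterpart in replicate 2, while in replicate 2 these shares were 99.9% and 82.0%. Promoters were found again more often than other regions of the same signal decile: in signal decile 5 of replicate 1, 86.9% of promoter regions and 46.6% of other regions touched a region of replicate 2. Over the 25612 regions paired between the replicates, peak signals had a Spearman correlation of 0.885 across regions, which are not independent replicates. When the 14171 strongest regions of each replicate were compared with the other's whole list, an alternative chosen after seeing the data, the shares were 92.5% for replicate 1 and 99.0% for replicate 2. Since the share rose with peak signal, keeping the strongest regions raises it by construction. These values therefore do not show how far the unequal length of the lists matters.

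**Figure D1:**
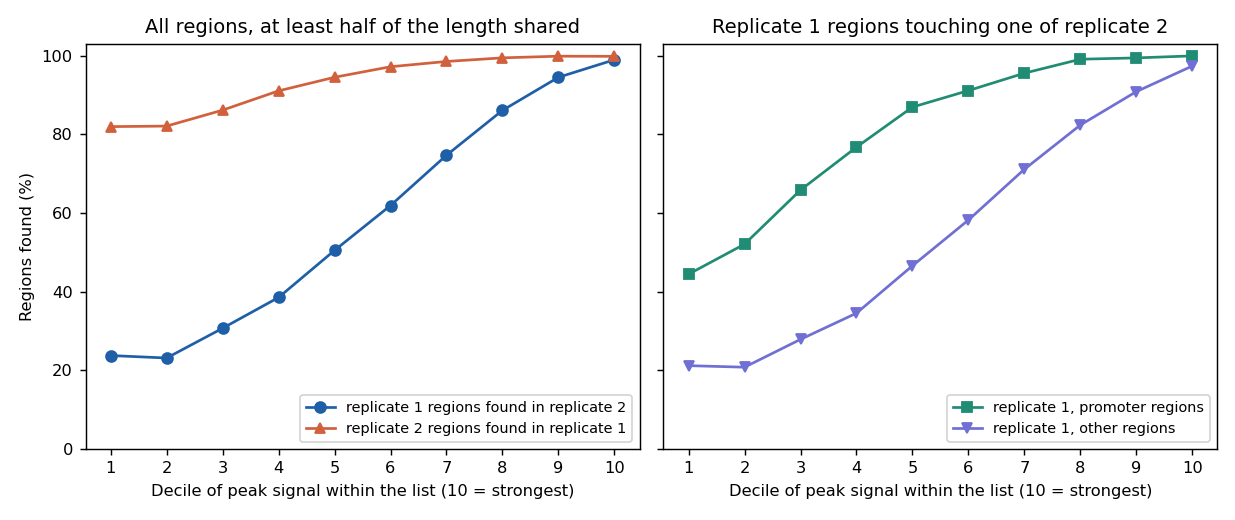
Share of regions (%, vertical axis) found in the other replicate by decile of peak signal within the list (horizontal axis, 10 is the strongest). The left panel counts regions covered over at least 50% of their length in either direction, from 23.7% to 99.0% for replicate 1 and from 82.0% to 99.9% for replicate 2. The right panel splits replicate 1 into promoter and other regions that touch any region of replicate 2, with promoters higher in each decile, as at 86.9% against 46.6% in decile 5.

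Promoters of the pan-neuronal, synaptic and activity-regulated lists were all accessible in the joint list of newborn forebrain. The same held for the cell division and housekeeping lists, so full accessibility is not particular to neuronal genes. All 21 pan-neuronal genes had an accessible promoter in the joint list and in both replicates (95% Wilson interval 84.5% to 100%), against 13047 of all 21827 protein-coding genes (59.8%). Among the 21 were Nrxn1, a presynaptic adhesion protein, with a peak signal of 21.2, Syt1, the calcium sensor of synaptic vesicle release, at 20.1, and Rtn1, a reticulon of the neuronal endoplasmic reticulum, at 16.5. All 22 genes for synaptic receptors and ion channels were accessible, led by Hcn1, a pacemaker channel, at 20.9, Scn2a, a voltage-gated sodium channel, at 19.9, and Kcnq3, a potassium channel of the M-current, at 14.3. All 21 activity-regulated genes were accessible in the joint list and in each replicate, led by the phosphatase gene Dusp1 at 19.7, the postsynaptic scaffold gene Homer1 at 17.7, and Nptx2, a secreted pentraxin, at 17.1. In replicate 2, 20 of the 22 channel and receptor genes were accessible, without Scn1a and Scn3a. Each of these 3 lists lay above the central 95% of 10000 random gene lists of the same size, at percentiles of 100. With the 5′ end of each gene as the only TSS, 77.3% of the channel and receptor genes were accessible, at the 97.4th percentile, which is inside the central 95%. Signals are those of a gene's strongest promoter region, which can lie at a TSS inside the gene. For Nrxn1, Rtn1, Scn2a and Homer1 it lay over 500 bp from both ends of the gene. The same held below for Foxp1, Aldh1l1, Enpp2, Pitx2, Rora and Krt10.

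Genes of telencephalic neuronal lineages were accessible as well. Of 21 genes of glutamatergic cortical neurons, 19 (90.5%, interval 71.1 to 97.3) had an accessible promoter, with 19 in replicate 1 and 16 in replicate 2, at the 99.9th percentile of random lists. The strongest were Tle4, a corepressor marking deep cortical layers, at 16.1, Zfpm2, a GATA cofactor, at 13.7, and Rorb, a nuclear receptor of layer 4 neurons, at 13.6. Genes with no region of the joint list at a TSS are called closed, which does not exclude weaker accessibility. Closed were Fezf2, a regulator of subcortical projection neurons, which was accessible in replicate 1 and in the looser joint list, and Slc17a7, a vesicular glutamate transporter. Of 24 genes of GABAergic and ganglionic eminence lineages, 20 (83.3%, interval 64.1 to 93.3) were accessible, at the 99.7th percentile. Foxp1, a forkhead factor of striatal neurons, reached 15.6, the interneuron homeobox gene Arx 15.4, and the zinc finger gene Sp9 14.0. Also closed were the medial ganglionic eminence genes Lhx6, Lhx8 and Nkx2-1 and the neuropeptide gene Sst, of which Sst alone was closed in the looser joint list, where 23 of the 24 were accessible. The replicates differed most in this list, with 19 genes accessible in replicate 1 and 13 in replicate 2. Dlx1, Dlx6, Sp8, Gsx2, Ascl1, Zfhx3 and Npy were accessible in replicate 1 alone, and Gad1, which encodes a GABA-synthesising enzyme, in replicate 2 alone. The GABAergic list stood at the 69.6th percentile when random lists were matched on promoter CpG content and at the 47.0th with replicate 2 alone, and also fell inside the central 95% with replicate 1 alone, with the conservative list and with 5′ gene ends. The glutamatergic list fell inside it with 5′ gene ends, at 96.8, and with replicate 2 alone, at 97.2.

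Progenitor and cell cycle genes were accessible at the day of birth. Of 22 forebrain progenitor genes, 21 (95.5%, interval 78.2 to 99.2) had an accessible promoter, with 21 in replicate 1 and 19 in replicate 2. Id4, an inhibitor of bHLH factors, reached a signal of 14.4, Foxg1, the telencephalic forkhead factor, 13.0, and Sox9, a factor of radial glia, 13.0. Eomes, which marks intermediate progenitors, was the 1 closed member, and was accessible in the looser joint list. All 20 cell division genes were accessible in the joint list and in both replicates. Mcm3, a subunit of the replicative helicase, had a signal of 28.9, the kinetochore gene Cenpf 28.0, and the spindle checkpoint kinase gene Bub1 26.96. The Mcm3 promoter region spanned 20819840 to 20820595 on chromosome 1 (mm10) and the Foxg1 region 49383135 to 49384245 on chromosome 12. Both lists lay above the random lists, at percentiles of at least 99.98. Against CpG-matched random lists the cell division list stood at 91.3, inside the central 95%.

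Glial genes were accessible in part. Of 20 astrocyte genes, 16 (80%, interval 58.4 to 91.9) were accessible, with 15 in replicate 1 and 12 in replicate 2. Clu, the secreted chaperone clusterin, reached 16.4, the membrane protein gene Mlc1 15.6, and the folate enzyme gene Aldh1l1 15.4. Gfap and Aqp4, the intermediate filament and water channel of mature astrocytes, were closed, as were S100b and Gjb6. The list stood at the 97.0th percentile, inside the central 95%, and at the 99.9th of CpG-matched lists. It also lay above the central 95% with a promoter window of 1000 bp, at 98.8, and in the looser joint list, at 99.4. It lay inside in the other settings, down to 66.35 with replicate 2 alone. Of 20 oligodendrocyte lineage genes, 10 were accessible, with 8 and 7 in the replicates, at the 18.5th percentile. The accessible members included Ugt8a, an enzyme of myelin lipid synthesis, at 12.8, Olig1, a lineage bHLH factor, at 11.8, and Lhfpl3 at 10.1. The myelin genes Plp1, Mog, Mag and Mobp were closed, while Mbp and Cnp of the same list were accessible, Mbp in replicate 1 alone. The 20 housekeeping genes were all accessible in the joint list, 19 of them in replicate 2, led by B2m at 24.6, Rplp0 at 22.9 and Sdha at 22.8.

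Genes of non-neural cells of the brain had few accessible promoters. For microglia, 3 of 20 genes (15.0%, interval 5.24 to 36.0) were accessible in the joint list and in each replicate: Hexb, a lysosomal enzyme, at 11.2, Sall1, a zinc finger factor that neural progenitors also express, at 9.30, and Tmem119 at 7.71. Cx3cr1, P2ry12 and Csf1r, receptors typical of microglia, were closed. For endothelial and mural cells, 5 of 20 genes were accessible, which were Kcnj8, Notch3, Kdr, Cldn5 and Pdgfrb, with 2 in replicate 1 and 1 in replicate 2. Kcnj8, Notch3 and Kdr were accessible in neither replicate's own list. Pecam1, Cdh5 and Flt1 were closed. For choroid plexus and meninges, 7 of 20 genes were accessible, with 5 and 4 in the replicates, led by Enpp2, a secreted lysophospholipase, at 12.2, Zic1 at 10.6 and Col8a1 at 9.17. Ttr, the transthyretin gene of the choroid plexus, Otx2 and Folr1 were closed. These lists stood at the 0.015th, 0.09th and 1.57th percentiles, below the central 95%. The microglial list stood at 5.49 among CpG-matched lists, inside it, and in the looser joint list the endothelial and choroid plexus lists, with 10 and 12 accessible genes, were inside it as well, as was the choroid plexus list with a promoter window of 1000 bp.

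Hox genes and genes of midbrain, hindbrain and diencephalon were mostly closed in the joint list. Of 39 Hox genes, which pattern the hindbrain and trunk, 1 was accessible (2.56%, interval 0.454 to 13.2): Hoxa1, with a signal of 4.79 at 52158182 to 52158644 on chromosome 6. Replicate 1 had 1 accessible Hox gene, Hoxc13, and replicate 2 had 0. Of 20 midbrain and hindbrain genes, 3 were accessible, with 3 in replicate 1 and 0 in replicate 2. In the joint list these were Tph2, a serotonin-synthesising enzyme, at 9.35, Atoh1, a bHLH factor of the rhombic lip, at 5.78, and Barhl2 at 4.90. En1, Pax2 and the other 15 were closed. Barhl2 was accessible in neither replicate's own list, and En2, closed in the joint list, was accessible in replicate 1. Of 20 diencephalic genes, 7 were accessible, with 8 and 5 in the replicates, led by Sim1, a hypothalamic bHLH-PAS factor, at 17.7, Pitx2 at 14.1 and Rora at 13.6, while Gbx2, Lef1 and Otp were closed in the joint list. Lef1 was accessible in replicate 1, and Gbx2 and Lef1 in the looser joint list. All 3 lists lay below the random lists, at percentiles of 0, 0 and 1.43. With replicate 1 alone the diencephalic list stood at 5.44, and with a window of 1000 bp at 7.96, both inside the central 95%, and in the looser joint list 12 diencephalic, 13 midbrain and hindbrain and 11 Hox promoters were accessible, which left the Hox list alone of the 3 below the central 95%.

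Genes of other tissues served as a background of cell types not sampled on purpose. Of 20 liver genes 1 was accessible: Trf, which encodes transferrin and is also made by oligodendrocytes, at 9.67. Of 19 erythroid genes 3 were accessible: Tfrc, the transferrin receptor of many dividing cells, at 21.98, Gypa at 8.33 and Tal1 at 3.88. Neither replicate's own list held a promoter region of Tal1. The globin genes Hbb-bs, Hbb-bt and Hba-a1 were closed. Of 20 striated muscle genes 2 were accessible: Actn2, a sarcomeric actinin, at 22.8 and Mylpf at 13.9, while Myod1, Myog and Myf5, which specify muscle, were closed. Of 20 epidermal genes 2 were accessible, Krt10 at 12.8 and Perp at 7.70, and of 20 germ cell genes 3 were, the recombination gene Prdm9 at 22.8, Tex14 at 19.4 and Dazl at 14.3. Replicate 1 had 1, 2, 2, 2 and 3 accessible genes in these lists, in this order, and replicate 2 had 0, 1, 2, 1 and 3. The 5 lists lay below the random lists, at percentiles of 0.01 or less. The erythroid list stood at 6.27 among CpG-matched lists, inside the central 95%. A region near a TSS can belong to a neighbouring gene. The Tex14 region, at 87404018 to 87404868 on chromosome 11, ended before the gene's first base at 87405065. Which gene such a region serves was not tested.

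**Figure D2:**
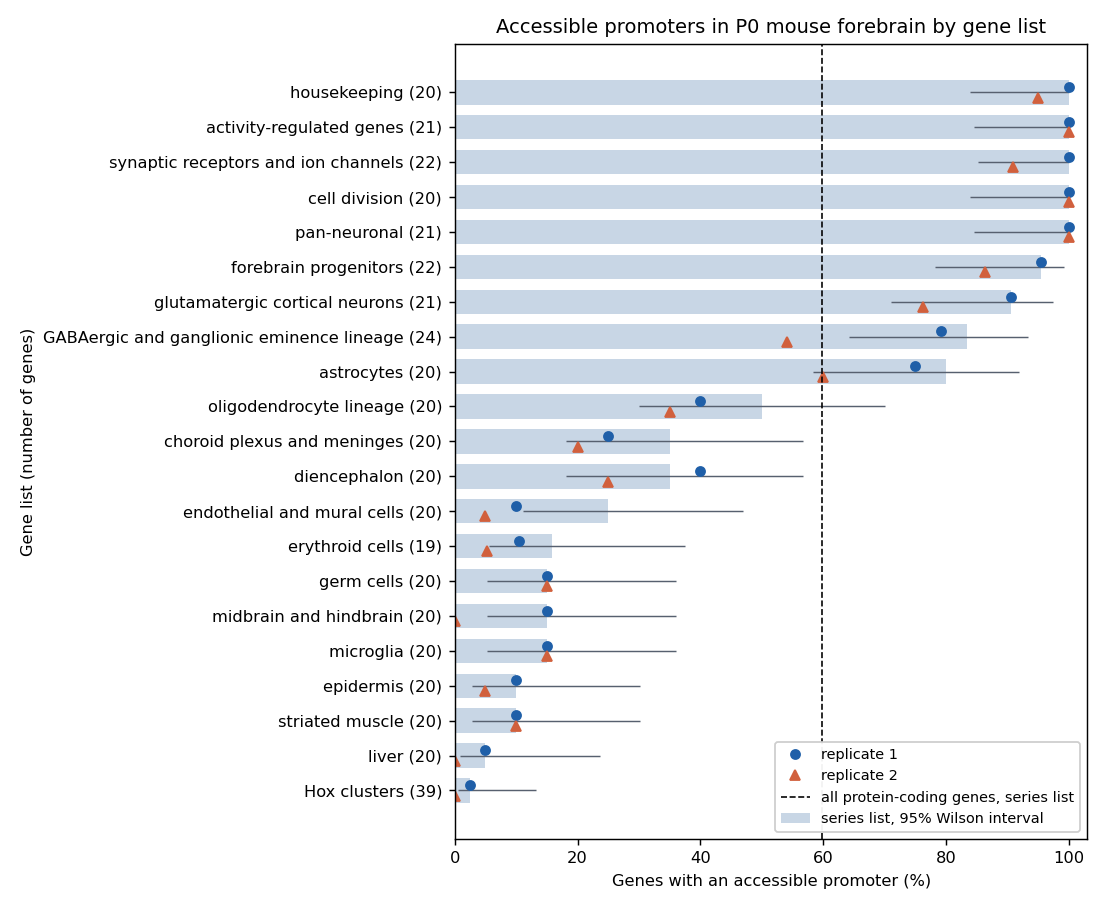
Genes with an accessible promoter (%, horizontal axis) in each of 21 gene lists (vertical axis, number of genes in brackets). Bars give the joint list with its 95% Wilson interval, circles replicate 1, triangles replicate 2, and the dashed line all protein-coding genes (59.8%). Neuronal, progenitor and cell division lists lie between 83.3% and 100%, and Hox genes at 2.56%.

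Taking all 21 lists, 8 lay above and 11 below the central 95% of random lists, and the astrocyte and oligodendrocyte lists lay inside it. In both replicates' own lists, 6 of the 8 and 10 of the 11 kept their side. The pan-neuronal, progenitor, activity-regulated and housekeeping lists stayed above it, and the Hox, liver, striated muscle, epidermal and germ cell lists below it, in each of the 8 settings computed. With 5′ gene ends 5 lists lay above, and in the looser joint list 7 lay below. Cldn5, Pdgfrb, Cnp and the members named here as closed, beyond the first 3 of each low list, were chosen after their values were seen. So were the members named as accessible in replicate 1 alone, apart from Neurod2, Fezf2 and Slc17a6. Of the other members named as closed, S100b, Gjb6, P2ry12, Flt1, En1, En2, Pax2 and Myod1 were accessible in the looser joint list.

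Distal regions gathered around progenitor, glial and activity-regulated genes. Of 36227 distal regions, 25601 (70.7%) had their nearest protein-coding TSS within 100 kb and were assigned to 9942 genes. Astrocyte genes had a median of 2.5 distal regions, led by Nfib with 12 and Nfia with 9, factors of the nuclear factor I family that act in gliogenesis. Oligodendrocyte lineage genes had a median of 3, led by Mbp, the myelin basic protein gene, with 8 and Opalin, a myelin membrane protein gene, with 7. Progenitor genes had a median of 3.5, led by Sox2, a neural stem cell factor, with 10 and the receptor gene Notch1 with 8. Activity-regulated genes had a median of 3, with 7 each at the immediate early genes Egr3 and Ier2. Glutamatergic genes had a median of 4, led by Bcl11b, a factor of subcortical projection neurons, with 10 and the bHLH gene Neurod2 with 8. GABAergic genes had a median of 3, with 8 each at Foxp1 and Meis2. In replicate 1 the medians of these lists, in the order given, were 2, 3, 3, 2, 4 and 2, and in replicate 2 they were 1, 1, 2, 1, 1 and 1. These 6 lists lay above the central 95% of random lists matched on the space around each gene, at percentiles from 98.3 for the glutamatergic to 99.98 for the astrocyte list.

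In the joint list the other 15 lists lay inside the central 95% for distal regions. Pan-neuronal genes had a median of 3 (percentile 94.1, and 98.2 with replicate 1 alone, above the central 95%), led by Myt1l, a zinc finger factor of neuronal identity, with 15 and the growth cone gene Gap43 with 9. Synaptic receptor and channel genes had a median of 2 (percentile 54.7), led by the calcium channel genes Cacna1e with 13 and Cacna1c with 12. Diencephalic, endothelial and midbrain and hindbrain genes had medians of 2, choroid plexus genes 1.5, microglial and germ cell genes 1, and cell division and muscle genes 0.5. Hox, erythroid, liver, epidermal and housekeeping genes had medians of 0. In replicate 2 the medians of all 15 lists were between 0 and 1. The progenitor, astrocyte, oligodendrocyte, glutamatergic and activity-regulated lists were also above the random lists in replicate 1, and the progenitor list, at the 99.9th percentile, and the astrocyte list, at 98.4, in replicate 2. With the conservative joint list the glutamatergic, GABAergic and progenitor lists fell inside the central 95%, and the astrocyte list was the 1 list above it in each setting computed. The glutamatergic list also fell inside it with assignment up to 500 kb, and without matching on surrounding sequence 12 lists lay above it.

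Some genes had distal regions in large number. Frmd4a, a scaffold gene of cell polarity at 4017717 to 4614043 on chromosome 2, had 26 in the joint list, 19 in replicate 1 and 15 in replicate 2. Pde4d, a cyclic AMP phosphodiesterase gene, followed with 23, the transcriptional repressor gene Bach2 and the nuclear corepressor gene Ncor2 with 22 each, and Tiam1, a Rac exchange factor gene, and Gse1 with 21 each. Kalrn, a Rho exchange factor gene of dendritic spines, had 20, and Ank3, which organises the axon initial segment, Maml3, a Notch coactivator gene, and Tnr, an extracellular matrix gene, had 19 each. The next 10 genes, Gramd1b, Shank2, Zbtb20, Zfp516, Ank2, Auts2, Dpp6, Gm26897, Lingo1 and Usp29, had 16 to 18. Every one of these 20 genes had distal regions in both replicates, from 11 to 19 in replicate 1 and from 4 to 15 in replicate 2. No test was attached to single genes, and the counts were not corrected for gene length.

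The 5 regions with the highest peak signal were intergenic and narrow, at 245 to 407 bp against a median of 723 bp. The first, with a signal of 55.3, spanned 143482936 to 143483180 on chromosome X. It lay 35530 bp from the nearest protein-coding TSS, that of Pak3, a kinase gene of synaptic signalling. The next reached 54.1 at 69355469 to 69355735 on chromosome 2, 12985 bp from Abcb11, the bile salt transporter gene. The regions ranked 3 and 5, at 60042765 to 60043138 on chromosome 5 and 96077546 to 96077952 on chromosome 10, had signals of 43.6 and 39.5. The region ranked 4, at 40.4, spanned 3964423 to 3964690 on chromosome 2, 53183 bp from Frmd4a. All 5 were also in both replicates' lists, where their signals ran from 36.5 to 54.4. Matches to the mitochondrial genome covered 89.6% and 86.5% of the regions on chromosomes 5 and 10 and 48.3% of that near Abcb11, and 0% of the other 2.

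Sites of CTCF, the insulator protein that anchors chromatin loops, had the highest summit-to-flank ratio at distal regions among the 19 sequence motifs searched. The CTCF consensus was present in windows reaching 100 bp to either side of the summit in 8.52% of 36211 distal regions (95% interval 8.24 to 8.81) and in 0.352% of flanking windows, a 24.2-fold excess, with 24.4-fold in replicate 1 and 20.2-fold in replicate 2. The RFX site, bound by regulators of ciliary genes, was present at 5.27% of summits (5.04 to 5.504), a 4.64-fold excess. The NFI half-site TTGGCA was present at 20.4%, 2.00-fold above the flanks, and the octamer ATGCAAAT of POU factors such as Pou3f2 at 2.76%, 2.20-fold above them. The E-boxes of the proneural bHLH factors were common: CAGATG, the NeuroD and Neurog type, at 25.1% of summits (1.61-fold) and CAGCTG, the Ascl1 type, at 21.3% (2.29-fold). GGGCGG, bound by SP and KLF factors, was 3.06-fold above the flanks and the ETS site 1.66-fold. The rarer EGR, NRF1 and full NFI sites, at 38, 38 and 26 summits, were 5.07-fold, 4.22-fold and 5.20-fold above them. The full NFI site was 6.29-fold above the flanks in replicate 1 and 2.40-fold in replicate 2, and the ETS site 1.87-fold and 2.87-fold, but 1.36-fold in the looser joint list. With flanks at 500 bp the EGR and full NFI ratios were 2.53 and 3.06, and narrower summit windows gave 41.6 for CTCF, 7.24 for RFX and 3 for EGR.

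Of the other 8 motifs, 7 had ratios below 1.5 at distal summits. The GATA site had a ratio of 0.653, the T-box site 0.623 and the PU.1 site of microglia and other myeloid cells 0.898. The SOX site had a ratio of 0.973, the AP-1 site 1.21 and the MEF2 site 1.26. The highest of 10 shuffled versions reached 1.17 for SOX, 1.18 for AP-1 and 0.606 for MEF2. The homeodomain site TAATTA of Dlx and Lhx factors had a ratio of 1.18 in the joint list, 1.28 in replicate 1 and 0.829 in replicate 2, on either side of 1, against 0.782 for the highest shuffled version in the joint list. The HNF1 site of liver and kidney factors was too rare for its ratio to be read: it was found in 0.00138% of flanking windows and at 0 of 36211 summits, which allows a share of up to 0.00828%, above that of the flanks. In all, 11 of the 19 motifs had a ratio of at least 1.5. Summit windows were richer in G and C than the flanks, at 50.2% and 44.8%. For 6 of the 11, which were CTCF, RFX, the NFI half-site and full site, POU and NRF1, the ratio exceeded the highest among 10 shuffled versions of the same sequence, and for CAGATG, CAGCTG, GGGCGG, ETS and EGR it did not.

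At promoter summits the NRF1, ETS and GGGCGG motifs stood further above the flanks than at distal summits. The NRF1 site, of a regulator of mitochondrial and housekeeping genes, was 47.6-fold more frequent at the summits of 12930 promoter regions than in their flanks, at 1.66% (1.45 to 1.89). The ETS site was present at 7.05% of promoter summits, a 24.3-fold excess, the EGR site at 0.974%, 10.5-fold, and GGGCGG at 61.6%, 7.97-fold. CTCF (3.89-fold), RFX (1.92-fold) and the full NFI site (2.67-fold, at 4 summits) were also above the flanks, making 7 motifs with a ratio of at least 1.5, each of which also reached it in distal regions. TAATTA, at 0.184, and the GATA site, at 0.198, were scarcer at promoter summits than in their flanks. The replicates gave 47.6-fold and 41.1-fold for NRF1 and 26.6-fold and 26.7-fold for ETS. With flanks at 500 bp the ratios were 20.4 for NRF1, 16.0 for ETS, 3.41 for EGR and 3.10 for GGGCGG, and narrower summit windows gave 75.3 for NRF1. Neither shuffled versions nor base composition were computed for promoters.

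**Figure D3:**
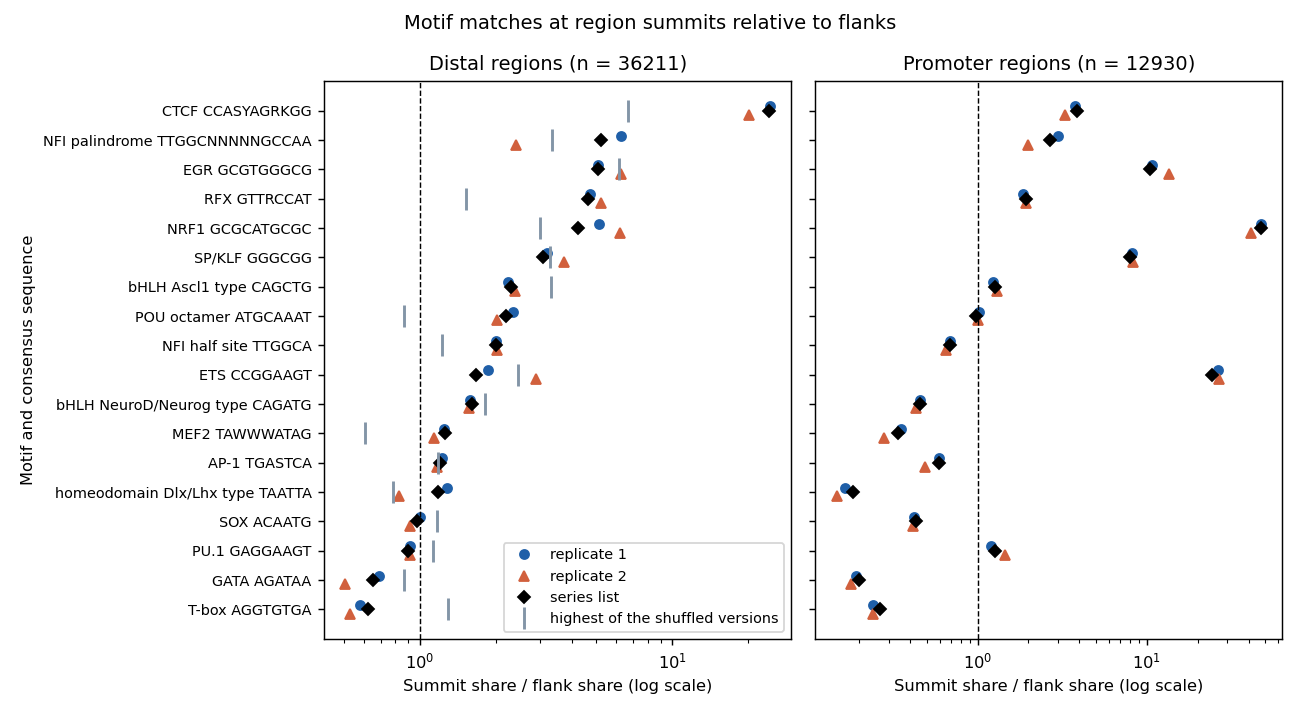
Share of summit windows with a motif divided by the share of flanking windows (horizontal axis, log scale) for 18 motifs (vertical axis) in distal regions (left, 36211) and promoter regions (right, 12930). Diamonds give the joint list, circles replicate 1, triangles replicate 2, and grey ticks the highest of 10 shuffled versions, drawn for distal regions. CTCF reaches 24.2 in distal regions and NRF1 47.6 at promoters, and the HNF1 site, with 0 matches at summits, is not drawn.

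Regions called in 1 replicate alone were weaker than shared regions and lay mostly outside promoters. In replicate 1, 17785 regions (40.1%) touched no region of replicate 2, with a median signal percentile of 27.01 against 68.1 for shared regions, and 6.51% of them were promoters against 43.2%. In replicate 2, 1751 regions (6.18%) touched no region of replicate 1, with a median signal percentile of 19.0 against 52.8 for shared regions, and 6.68% of them were promoters against 43.1%. Promoters of 862 protein-coding genes were accessible in replicate 1 alone, and of 100 in replicate 2 alone, beside 11899 accessible in both. Those of replicate 1 included Neurod2, Fezf2 and Slc17a6, a vesicular glutamate transporter gene, and those of replicate 2 included Gad1, the oligodendrocyte precursor receptor gene Gpr17 and the forkhead gene Foxd1. Of the 17785 regions, 80.9% touched a region of the looser list of replicate 2, and 3399 touched neither list. With the looser lists on both sides, 37046 regions were called in replicate 1 alone and 9924 in replicate 2 alone.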

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

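The tests that set promoter and other regions apart, and those that split the motifs into 2 groups, were chosen after the result was seen.

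The lists that rank peaks by IDR, which no comparison above used, held intervals that the thresholded lists lacked. In replicate 1, 54 intervals past the IDR threshold of 0.05 touched no thresholded region, and in replicate 2 there were 67. Of these, 16 and 18 lay on unplaced scaffolds and 38 and 49 on assembled chromosomes, among them 24541953 to 24542230 on chromosome 9, with a signal of 45.7 in replicate 1. Matches to the mitochondrial genome argue against nuclear copies of mitochondrial DNA as the source of the whole set, since 2.30% of the placed intervals matched over at least 50% of their length, 1 interval per replicate at 24611587 on chromosome 1. Repeat sequence remains a candidate explanation: the median share of repeat-masked bases was 30.6% (interquartile range 10.2 to 64.7) in the missing intervals and 8.67% (4.20 to 14.6) in 2000 regions of the joint list. The median was 18.6% in replicate 1 and 35.4% in replicate 2, and no biological explanation was tested.

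The excess of regions called in replicate 1 alone was weighed against 3 explanations. Closeness to the calling threshold may account for part of it, since 80.9% of these regions touched the looser list of replicate 2, but the looser lists on both sides did not remove the excess, with 37046 regions in replicate 1 alone against 9924 in replicate 2 alone and 59.9% of replicate 1 regions found in replicate 2 in place of 58.3%. A different mix of cell types in the 2 pools also stays open: after allowing for signal, regions of 4 of 21 gene lists were found in replicate 2 more or less often than those of random gene lists, namely midbrain and hindbrain (−18.6 points), liver (−19.2), striated muscle (−26.3) and housekeeping (18.4), on 38, 9, 16 and 41 regions, where about 1 is due to chance. With promoter and other regions set apart the number for a different mix of cell types was again 4, with germ cells (22.4) in place of housekeeping, and no list of a forebrain cell type was among them in either test. Lower sequencing depth of replicate 2 cannot be told apart from the rest, as the median −log10 q at equal signal was 0.978 times that of replicate 1, past the bound set in advance against depth, but that bound was wrong: the joint list reached 0.870 times the sum of both replicates, so the measure misses a known sum by more than the margin, and the signal scale of separate lists is not stated.

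The excess of motifs at distal summits was weighed against base composition of the summit windows, the 1 technical explanation tested. For all 11 motifs together the question cannot be told apart, since 6 exceeded each of 10 shuffled versions of themselves and 5 did not. Base composition is argued against for CTCF, RFX, the NFI half-site and the POU octamer, whose ratios were at least 1.63 times the highest of their shuffled versions. For CAGATG, CAGCTG, GGGCGG and the ETS site it remains a possible explanation, since the ratio was at most 0.935 times that highest value. Their ratios lay above the medians of their shuffled versions, at 1.23, 1.56, 2.79 and 1.29, which does not settle it. The motifs were put into these groups by the same comparison with shuffled versions, so the grouping itself adds no evidence. The EGR, NRF1 and full NFI sites, each with under 100 summit matches, were left out of both groups. Motifs with a ratio below 1.5 were not weighed here. Among those, MEF2 (1.26 against 0.606), TAATTA (1.18 against 0.782) and AP-1 (1.206 against 1.185) also exceeded the highest of their shuffled versions. Absence from the groups therefore does not mean that a motif had no excess beyond base composition. Binding of the proteins was not measured, and no biological explanation was tested.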

How the results depend on the processing

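The alternatives that compared the strongest regions in equal number were chosen after the result was seen. No gene list crossed from one side of the random lists to the other, and no motif with a ratio of at least 1.5 fell below 1. Ratios near 1 crossed it: distal TAATTA was 0.829 without replicate 1, distal PU.1 1.01 in the looser list, and promoter POU 1.01 to 1.31 in 4 alternatives. Counting every peak line gave 106215 for the joint list, 90818 for replicate 1 and 63428 for replicate 2, because intervals repeat once per summit. The share of replicate 1 regions found in replicate 2 was 59.9% at 1 bp of overlap and 57.3% with 50% of both regions. With the looser lists it was 59.9%, and for the 14171 strongest regions 92.5%, a choice that raises the share by construction. For replicate 2 in replicate 1 these shares were 93.8%, 89.7%, 84.9% and 99.0%. The signal correlation was 0.882 at 1 bp, 0.853 with the looser lists and 0.919 with −log10 q in place of signal. The promoter share was 13.7% in the looser list, 37.4% in replicate 1 held to its strongest regions, as many as in replicate 2, and 28.5% to 40.9% with either replicate left out. Promoter lists above the random lists numbered 5 with 5′ gene ends, where each gene offers fewer sites, and 6 to 7 with either replicate left out. Lists below numbered 7 in the looser list and 10 to 11 with either replicate left out. Distal lists above numbered 12 without matching on surrounding sequence, 3 in the conservative list and 2 to 6 with either replicate left out. Regions called in 1 replicate alone numbered 37046 and 9924 with the looser lists. Except where the construction is stated, the cause was not tested. The motif counts of 11 and 7 stayed within 1.5 times under each alternative. For single gene lists and motifs, 98 of 147 promoter values, 78 of 147 distal values and 111 of 224 motif ratios moved by less than the spread between replicates or their interval, where the motif ratios include 8 of the HNF1 site, each 0 and too rare to show stability. The alternative that kept a fixed number of the strongest regions removes nothing, as each replicate's list is shorter than that number, and gave no value. No paired analysis was possible because the series has 1 group. The unknown read depth limits how absence from a list can be read, above all in replicate 2.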

Other observations

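The tests of gene families, of mitochondrial matches and of motifs by signal decile were chosen after the result was seen, and those of the 2 lineage hypotheses before.

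Most genes of 2 axon guidance families had accessible promoters. Of 29 semaphorins and plexins, ligands and receptors that steer axons, 26 had an accessible promoter, with 26 in replicate 1 and 24 in replicate 2, at percentile 99.98 of random lists. Plxnb3, Sema3b and Sema3g were closed. Of 22 ephrins and Eph receptors 21 were accessible, with 21 and 17 in the replicates, at percentile 100 of random lists and 90.8 of CpG-matched lists, which is inside the central 95%. Epha2 was closed in the joint list and accessible in replicate 1. Of 15 GABA-A receptor subunits 13 were accessible, with 13 and 11 in the replicates, at percentile 98.4, without Gabra6 and Gabrb1, the latter accessible in replicate 1. Of 14 serotonin receptors 12 were accessible, with 11 and 9 in the replicates, at percentile 97.9, without Htr1d and Htr3b. These 2 families also lay above the central 95% of CpG-matched lists. Inside the central 95% of random lists were the ionotropic glutamate receptor subunits, with 13 of 16 accessible at percentile 96.0 and without Grik5, Grin2c and Grin3b, and the nicotinic subunits, with 6 of 16 at 3.97 and with 6 and 4 in the replicates. The clustered protocadherins, cell adhesion genes from which single neurons choose a few, had 6 of 56 promoters accessible, at percentile 0, with 8 and 4 in the replicates.

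Developmental factor families were open in part, and receptor families of the nose were closed. Of 6 Dlx genes, Dlx1, Dlx2, Dlx5 and Dlx6 were accessible, with 4 and 2 in the replicates, at percentile 61.5, and of 19 Sox genes 13 were, with 12 and 11 in the replicates, at 76.7. Of 9 Pax genes, Pax6 and Pax9 were accessible, of 14 Nkx genes Nkx3-1 and Nkx6-1, of 6 Gata genes Gata6, and of 6 Irx genes Irx2. Of 44 Fox genes 22 were accessible, of 15 Pou genes 9, of 16 T-box genes 5, of 8 Lhx genes 4, of 7 Neurod and Neurog genes 5 and of 5 Zic genes 4. In replicate 1 these 6 families had 20, 10, 4, 3, 5 and 4 accessible genes, and in replicate 2 they had 18, 8, 2, 1, 2 and 4. Nkx genes had 2 and 1. The Pax, Nkx, Gata, Irx and T-box families lay below the random lists, at percentiles from 0.045 to 2.47, and the Dlx, Sox, Fox, Pou, Lhx, Neurod and Neurog, and Zic families inside their central 95%. Among CpG-matched lists the Sox family, at 0.515, and the Fox family, at 0, lay below it as well. For distal regions, the Dlx and Sox families, each with a median of 3, stood at percentiles of 99.7 and 99.0 of matched random lists, above the central 95%, and the GABA-A receptor subunits, with a median of 0, at 2.22, below it, while the other 20 families lay inside it. Of 1133 olfactory receptor genes 4 were accessible (0.353%, interval 0.137 to 0.904), of 328 vomeronasal receptor genes 2, of 49 keratin genes 2 and of 55 cytochrome P450 genes of families 2 and 3, 6. Olfactory receptors had 4 and 2 accessible in the replicates, vomeronasal receptors 1 and 1.

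Among the 100 strongest distal regions, 5 (5%, interval 2.15 to 11.2) matched the mitochondrial genome over at least 50% of their length, against 0 of the 100 strongest promoter regions and 0 of 2000 regions drawn from the joint list. From the weakest to the strongest decile of distal regions, the share of summits with the RFX site went from 3.67% to 8.62%. The share with the CTCF site was 6.07% in the weakest decile and 9.78% in decile 5, and from decile 6 to decile 10 it lay between 9.003% and 9.89%. The NFI half-site lay between 18.8% and 21.8%, with the lowest share in decile 10 and the highest in decile 7.

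The first hypothesis was that homeodomain sites may gather near GABAergic lineage genes, whose Dlx, Lhx and Arx factors bind TAATTA. In the joint list TAATTA was present at 10 of 89 distal summits of GABAergic genes (11.2%), spread over Dlx1, Dlx6, Gad2, Lhx6, Nkx2-1, Ascl1, Slc32a1 and Zfhx3, and at 1 of 91 summits of glutamatergic genes (1.10%), that of Cux2. The difference stood at percentile 99.7 among 10000 random divisions of the same genes. In replicate 1 it was 8.86% against 6.33%, at percentile 69.0, and in replicate 2 it was 2 of 26 against 0 of 35, at 98.3, so the replicates do not settle it.

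The second hypothesis was that the NeuroD and Neurog site CAGATG may gather near glutamatergic genes. It was present at 28 of 91 distal summits of glutamatergic genes (30.8%) and at 20 of 89 of GABAergic genes (22.5%), at percentile 90.2 among random divisions, inside the central 95%. Over all distal summits CAGATG was present at 25.1%, inside the 95% intervals of both shares (22.2 to 40.9 and 15.0 to 32.2). The shares were 31.6% against 24.1% in replicate 1 and 37.1% against 15.4% in replicate 2. Taken as GABAergic minus glutamatergic, the differences stood at percentiles of 12.8 and 3.05, also inside the central 95%.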
